A study of Culex quinquefasciatus and Culex pipiens molestus with 2 samples.

How the data were processed

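RNA was extracted with TRIzol from 30 females of a laboratory strain of each of 2 taxa, pooled per taxon, selected for polyadenylated RNA and made into non-directional Illumina libraries, per the labels' protocols. Each taxon had 1 library, so a taxon and its library cannot be separated, and the age, feeding state and time of collection of the females are not given in the sources used here. The labels tie no table to a taxon. Each table was given to the taxon whose name its abbreviation matches, Cxm to molestus and Cxq to quinquefasciatus, and every direction below rests on that link.

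The authors deposited, per transcript model, the count of uniquely assigned reads, and the total of each library stands in the file header. The listed counts summed exactly to that total, and models without reads were not listed, so an unlisted model was taken as 0 reads. RPKM values were deposited beside the counts, and recomputing them from count, model length and library total gave the same values within rounding. The percent of each model's length that was covered by reads was also deposited, per the file headers. The aligner, the counting tool, the filters and the release of the gene models are not given in the sources used here. Identifiers of the CPIJ form are those of the Culex quinquefasciatus genome project, as background. Models with 1 read covered 90 bases in both libraries, which gives the read length. Of the listed lengths, 89.1% were multiples of 3, as the lengths of coding sequences without untranslated regions are. The libraries do not keep strand, so reads of a gene and of an overlapping antisense gene cannot be told apart, and uniquely assigned reads undercount near-identical copies.

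The depth was 9.79 M reads for molestus and 10.17 M reads for quinquefasciatus. Levels were compared as the log2 ratio of (RPKM + 1), molestus over quinquefasciatus, over the 12789 of 16198 listed models with at least 1 RPKM in at least 1 library. Models with a ratio of at least 2-fold on that scale were counted. The pseudocount of 1 understates the ratio of low models. For single models the fold is the ratio of RPKM without a pseudocount, with an exact 95% interval from the conditional binomial distribution of the counts of both libraries (Clopper-Pearson). Shares of reads have exact Clopper-Pearson intervals. For a model at 0 reads in 1 library the fold is a lower bound against a floor of 3 reads. A count test such as the quasi-likelihood test needs replicates and was not run, and RPKM was kept as the main scale as set out before the data were examined.

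Before the data were examined, 28 gene lists were fixed as text patterns on the product descriptions, which 10033 of the 16198 models carry. A pattern can also take in models of other functions, such as myosins outside muscle in the muscle list. For each list the median log2 ratio is given with an exact order-statistic interval over its members. Its percentile is that among the medians of 10000 random lists of the same size, drawn outside the list and matched on mean expression in 20 bins, as a description of these libraries. The members at 0 reads in 1 library were also set to the floor of 3 reads. This moved the medians of 10 lists, by at most 0.23, and turned the sign of 0. The named genes followed a rule fixed at the same time. It took the 12 described models with the largest ratio in each direction at a minimum of 10 RPKM and 50 reads in the higher library, up to 4 abundant members and up to 2 with the largest ratio in each direction per list, and the 5 most abundant models of each library. Models named outside the rule are said to be so.

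The alternatives fixed beforehand were pseudocounts of 0.1 and 10, no filter and a minimum of 10 RPKM, rescaling by the median ratio, by TMM factors from the counts (1.09 for molestus and 0.919 for quinquefasciatus) or to the same sum without the 100 most abundant models of either library (116 models), a 4-fold threshold, a floor of 10 reads, and shares of summed RPKM. Further alternatives of 6 list patterns were added after seeing the data. The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.

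The procedure was tested on simulated Poisson counts for the same models and library sizes, with 200 models altered and 12401 compared. The altered models were drawn only from those with at least 50 expected reads and 10 RPKM, so their recovery does not speak for lower models. All 50 models in each of the 4 classes of altered models (3-fold and 8-fold, higher and lower) were counted in the right direction, and 0.566% of 12201 unaltered models were counted as at least 2-fold higher in either library. Of the simulated fold intervals with reads in both libraries and at least 10 in all, 95.3% held the true fold. A list of 3-fold higher models stood at percentile 100, and 10 unaltered lists stood between percentiles 9.44 and 96.4. The simulation holds counting error only and no difference between animals. The supplied gene table holds no CPIJ identifiers, so 0 models were matched to it, and positions in the genome were not used here.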

Results

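The polyadenylated RNA of females of 2 house mosquitoes was measured by RNA sequencing. Culex pipiens molestus is a form that breeds largely in enclosed urban water and can lay eggs without a blood meal, and Culex pipiens quinquefasciatus, the southern house mosquito, generally needs blood to lay. RNA of 30 females of a laboratory strain of each taxon was pooled into 1 library per taxon. The molestus library held 9.79 M (mega) uniquely assigned reads over 14834 listed transcript models, with a median of 94 reads per listed model. The quinquefasciatus library held 10.17 M such reads over 15438 listed models, with a median of 86 reads. A floor of 3 reads corresponded to 0.307 RPKM (reads per kilobase of model and per M assigned reads) in the molestus library and 0.295 RPKM in the quinquefasciatus library for a model of 1 kb. Gene names below are the product descriptions of the deposited tables, and each CPIJ identifier names 1 transcript model.

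The comparison asked how the transcript levels of females of the 2 taxa differed. Genes of DNA replication and cell division were higher in the molestus library, with a median log2 ratio of 1.69 over 69 models, and histones, the proteins that package DNA, had a median of 1.78 over 28 models. Trypsins and chymotrypsins, which digest protein in the midgut, were lower there, with a median of -1.15 over 63 models. Sugar-digesting enzymes had a median of -1.44 over 28 models, and odorant binding and chemosensory proteins, small carriers of odours in the antennae, had a median of -1.44 over 17 models. Cytosolic ribosomal proteins had a median of -0.81 over 108 models and made up 13.6% (13.58 to 13.62) of the reads of the molestus library against 25.0% (24.97 to 25.02) of the quinquefasciatus library. With 1 library per taxon these differences had no replicate check, and no p-value was computed. All intervals are 95% intervals, those of folds and shares cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. Which table belongs to which taxon rests on the abbreviations Cxm and Cxq in the names of the tables.

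Across the 12789 models with at least 1 RPKM in at least 1 library, 2914 (22.8%) were at least 2-fold higher in the molestus library and 2303 (18.0%) were at least 2-fold higher in the quinquefasciatus library, on the log2(RPKM + 1) scale. The other 7572 models lay within 2-fold. The counting interval of the fold lay wholly on the same side of 1 for 2869 and 2224 of these models, and wholly beyond 2-fold for 2128 and 1601. With models of 0 reads set to the floor of 3 reads, the counts were 2833 and 2139. The balance of the counts depended on the scaling. The median log2 ratio was 0.18 over the compared models and 0.27 over the 10767 models with at least 1 RPKM in both libraries. After rescaling by the median ratio, which shifted the ratios by -0.30, 2002 models were higher in the molestus and 2942 in the quinquefasciatus library, and trimmed mean of M-values (TMM) factors, a shift of -0.24, gave 2144 and 2818. Rescaling to the same sum without the most abundant models gave 2142 and 2821. With all models included, summed RPKM was 780178 in the molestus and 895078 in the quinquefasciatus library, which as a scale would shift the ratios the other way. Across models, Pearson's r was 0.838 and Spearman's rho 0.826 on that scale, and genes are not independent replicates.

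**Figure D1:**
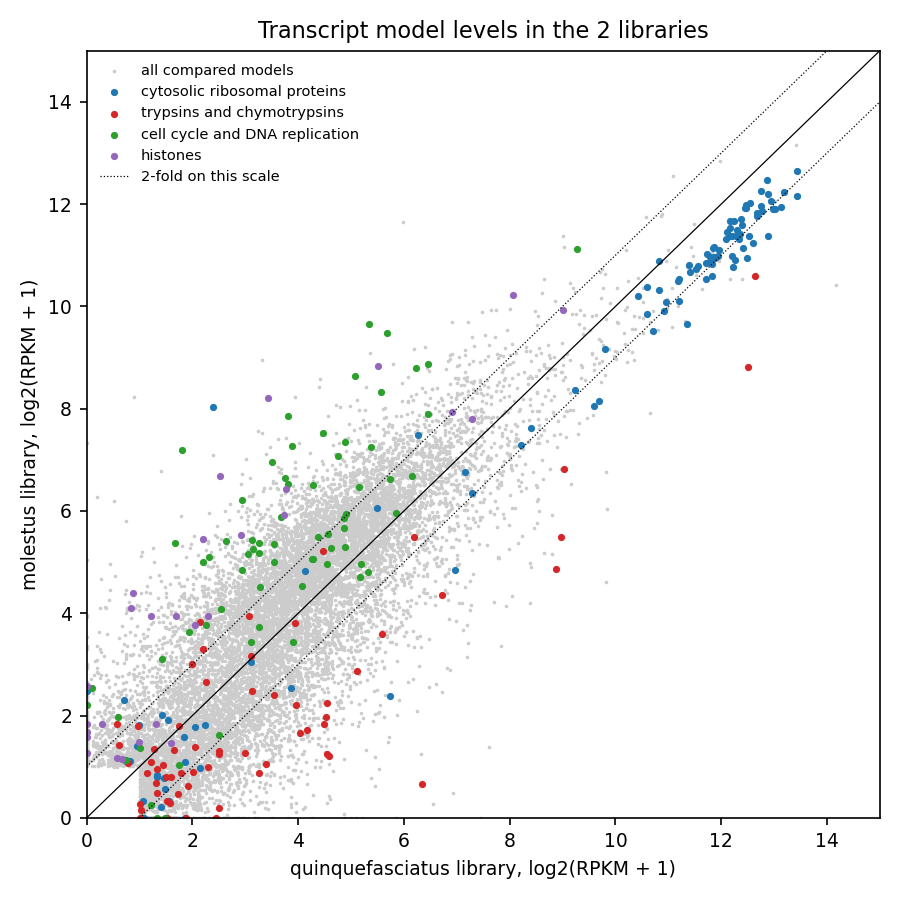
Level of each of 12789 compared transcript models in the quinquefasciatus library (x axis) and the molestus library (y axis), both as log2(RPKM + 1), with 1 point per model, the diagonal at equal levels and dotted lines at 2-fold. Cell cycle and histone models lie mostly above the diagonal (medians 1.69 and 1.78), and ribosomal proteins and trypsins mostly below it (medians -0.81 and -1.15), as they also did after rescaling by the median ratio or TMM.

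Of the 69 compared models of the cell cycle and DNA replication list, 44 were at least 2-fold higher in the molestus library and 2 in the quinquefasciatus library. The list median of 1.69 (exact interval over members 1.04 to 2.12) lay above all 10000 random lists matched on expression, whose median was 0.34. With the 3 members at 0 reads in 1 library set to the floor, the counts were 43 and 0 and the median 1.54. Both subunits of ribonucleotide reductase, the enzyme that makes the building blocks of DNA, were among its abundant members. The large subunit (CPIJ005992) was 14.1-fold higher (13.3 to 15), at 709 against 50.2 RPKM, and the M2 subunit (CPIJ002337) was 20.5-fold higher (18.7 to 22.5), at 804 against 39.3 RPKM. Cdt1 (CPIJ009958), which loads the replicative helicase onto DNA, was 58.3-fold higher (44.6 to 77.8), and the helicase subunit mcm7-A (CPIJ000160) was 17.9-fold higher (16.0 to 20.1). Cyclin-B (CPIJ010895) and cyclin-A (CPIJ013567), which drive entry into mitosis, were 3.64-fold (3.56 to 3.71) and 5.40-fold (5.05 to 5.79) higher. The members furthest the other way at the naming minimum were a mitochondrial ribosome recycling factor (CPIJ004545), taken in by the list's text pattern, at 0.70-fold of the quinquefasciatus level (0.58 to 0.84), and a cyclin-dependent kinase regulatory subunit (CPIJ006105) at 0.710-fold (0.515 to 0.973). The whole list held 1.52% (1.51 to 1.53) of molestus and 0.347% (0.343 to 0.351) of quinquefasciatus reads.

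Histones were at least 2-fold higher in the molestus library for 21 of 28 compared models and in the quinquefasciatus library for 0. Their median was 1.78 (1.27 to 2.61), and 1.69 with the 5 members at 0 reads in 1 library set to the floor (17 and 0 at least 2-fold higher). It was 2.75 at a pseudocount of 0.1. The main median lay above all 10000 matched lists. Histone H1E (CPIJ010358), a linker histone, was 30.2-fold higher (24.3 to 38.1). Late histone H2A.2.1 (CPIJ020168), outside the list's text pattern, was 31.8-fold higher (19.7 to 55.0). The variant histones H2A.x (CPIJ001452) and H2AV (CPIJ008494) were 10.2-fold (8.75 to 11.9) and 4.48-fold (4.21 to 4.77) higher, and histone H3.3 (CPIJ017187) was 1.89-fold higher (1.79 to 1.99). Histone genes occur in near-identical copies, so the division of reads among single histone models is uncertain in tables of uniquely assigned reads. Both libraries were selected for polyadenylated RNA, so these values speak for polyadenylated histone transcripts and not for all histone transcripts.

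Germline and ovary genes went in both directions, with 10 of 18 models at least 2-fold higher in the molestus library and 4 in the quinquefasciatus library. Their median of 1.26 had an interval that included 0 (-0.87 to 1.59), and its percentile among matched lists was 99.95. Bicaudal C (CPIJ005456), an RNA-binding protein of the developing egg, was 15.1-fold higher in the molestus library (13.3 to 17.1), and bicaudal D (CPIJ012635), part of the transport of RNA into the oocyte, was 5.10-fold higher (4.60 to 5.67). The piwi family, which silences transposons in the germline, split. Models CPIJ002459 and CPIJ017381 were 4.34-fold (4.17 to 4.52) and 3.04-fold (2.87 to 3.22) higher in the molestus library, while CPIJ002458 and CPIJ017382 were 3.20-fold (2.57 to 4.01) and 5.08-fold (4.36 to 5.93) higher in the quinquefasciatus library. As paralogs, these 4 models may lose reads that match several of them, and their single values are uncertain.

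Yolk and eggshell genes had a median of 0.09 (-0.74 to 1.53) over 9 models, which became negative under both rescalings (-0.19 by the median ratio and -0.14 by TMM) and was 0.87 over 6 models at a minimum of 10 RPKM, with 3 models at least 2-fold higher in the molestus library and 1 in the quinquefasciatus library. Vitellogenic carboxypeptidase (CPIJ008608), which is made in the fat body during yolk formation, was 2.54-fold higher in the molestus library (2.42 to 2.68), at 371 against 146 RPKM. The chorion transcription factor Cf2 (CPIJ011638) was 7.90-fold higher (6.86 to 9.14). Of 2 models named chorion peroxidase, an enzyme of the eggshell, CPIJ007711 was 2.96-fold higher in the molestus library (2.71 to 3.23) and CPIJ001764 was 2.63-fold higher in the quinquefasciatus library (2.38 to 2.90). The vitellogenin models, named here after their values were seen, were low in both libraries, at 1.26 against 2.06 RPKM for CPIJ002028 and 0.95 against 2.26 RPKM for CPIJ009271. Storage proteins, which hold amino acids in the hemolymph, were also low, with 4 compared models of at most 2.72 RPKM and a median of -0.82, -1.56 at a pseudocount of 0.1 and -0.10 without a filter.

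Trypsins and chymotrypsins were at least 2-fold higher in the quinquefasciatus library for 34 of 63 models and in the molestus library for 4. The median of -1.15 (-1.52 to -0.70) lay below all 10000 matched lists, and was -2.31 over 23 models at a minimum of 10 RPKM, -0.51 without a filter and -1.84 at a pseudocount of 0.1. Trypsin-2 (CPIJ005273) was 13-fold higher in the quinquefasciatus library (12.6 to 13.5), at 5835 against 448 RPKM, and trypsin-1 (CPIJ000835) was 4.10-fold higher (4.02 to 4.17), at 6370 against 1555 RPKM. Trypsin 5G1 (CPIJ004640) was 139-fold higher (63.6 to 380), from 6 molestus reads, and chymotrypsin-1 (CPIJ002518) 16.7-fold higher (14.6 to 19.2). An antichymotrypsin (CPIJ016298), an inhibitor that the list's text pattern took in, and trypsin-3 (CPIJ014650) were higher in the molestus library, by 3.89-fold (2.81 to 5.49) and 1.96-fold (1.5 to 2.57). Outside the list, the serine protease SP24D (CPIJ015368) was the most abundant model of the quinquefasciatus library by RPKM, at 18580 RPKM, and 13.6-fold lower (13.4 to 13.9) in the molestus library.

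Sugar digestion enzymes were at least 2-fold higher in the quinquefasciatus library for 16 of 28 models and in the molestus library for 2, with a median of -1.44 (-2.71 to -0.70) that lay below all matched lists. The median was -2.57 over 16 models at a minimum of 10 RPKM and -0.86 over 33 models without a filter. The maltase 1 models CPIJ019693 and CPIJ018570 were 19.1-fold (17.1 to 21.4) and 28.1-fold (19.8 to 41.3) higher in the quinquefasciatus library. A further maltase 1 model (CPIJ019691) had 1 molestus and 527 quinquefasciatus reads, a ratio of 507 (90.7 to 20078). An alpha-amylase (CPIJ016362), which cleaves starch, was 3.30-fold higher (3.06 to 3.55). The exceptions were the trehalases CPIJ006199 and CPIJ017949, which split the blood sugar trehalose, at 5.98-fold (5.50 to 6.5) and 4.59-fold (4.24 to 4.98) higher in the molestus library.

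**Figure D2:**
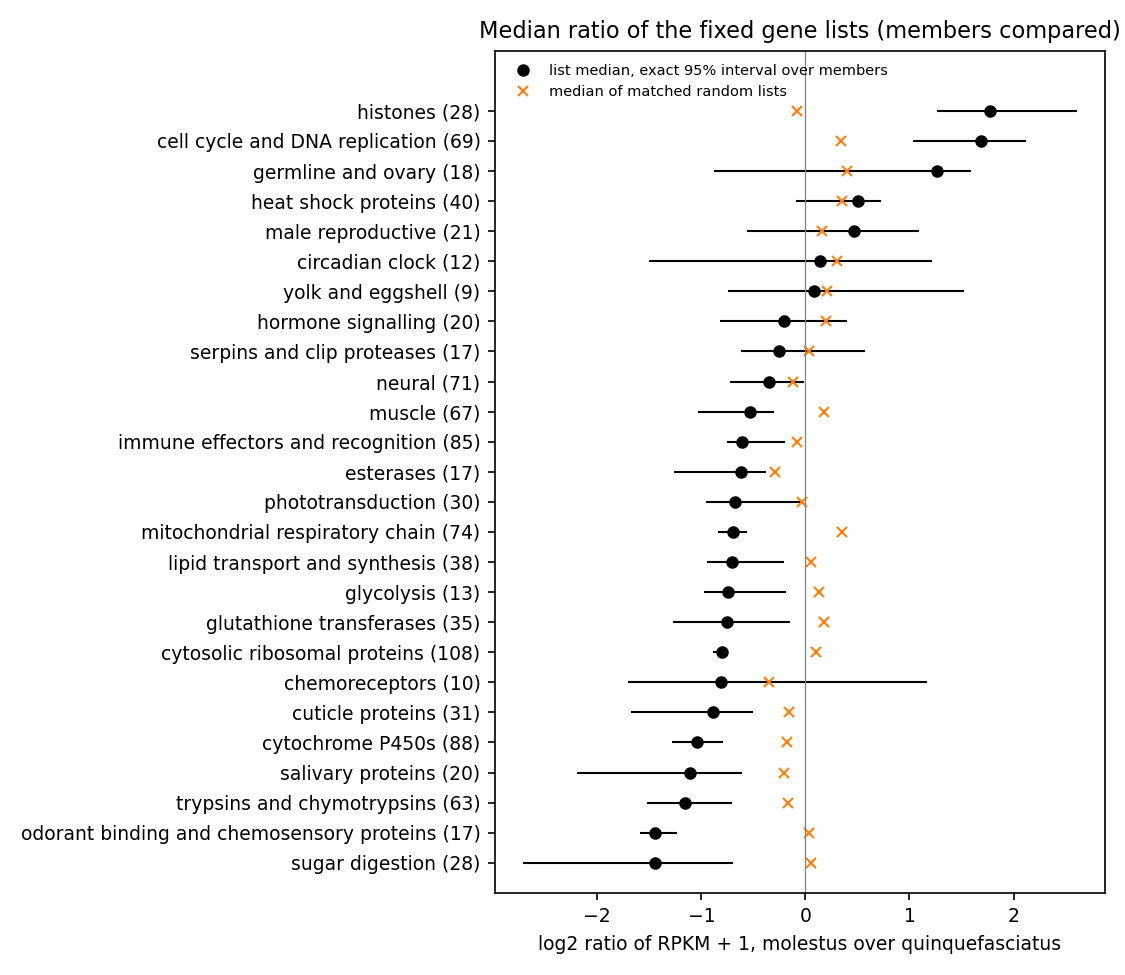
Median log2 ratio of RPKM + 1, molestus over quinquefasciatus, of the 26 gene lists with an interval (black points, with lines for the exact 95% interval over members) beside the median of expression-matched random lists (crosses), with the number of compared members in parentheses. Histones (1.78) and the cell cycle list (1.69) had the highest medians and sugar digestion and odorant binding proteins (both -1.44) the lowest, and the medians of circadian clock and yolk and eggshell genes changed sign under both rescalings.

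Odorant binding and chemosensory proteins were at least 2-fold higher in the quinquefasciatus library for 14 of 17 models and in the molestus library for 0, with a median of -1.44 (-1.59 to -1.23) at percentile 0.01 of the matched lists. The most abundant, general odorant-binding protein 99A (CPIJ017326), was 3.01-fold higher in the quinquefasciatus library (2.82 to 3.22), at 632 against 210 RPKM. Chemoreceptors, the membrane receptors of smell and taste, were mostly near the detection limit. Their text pattern also took in models named ionotropic glutamate receptor, such as CPIJ008619, which the neural pattern takes in as well. Of the 59 listed models of the chemoreceptor list 10 were compared, with 2 at least 2-fold higher in the molestus and 4 in the quinquefasciatus library and a median of -0.82 (-1.71 to 1.17). The median was -1.62 at a pseudocount of 0.1, -0.17 over 3 models at a minimum of 10 RPKM, -0.12 without a filter and -0.58 with the 3 members at 0 reads in 1 library at the floor.

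Genes of phototransduction, the response of the eye to light, had a median of -0.67 (-0.95 to -0.03) over 30 models at percentile 1.40. Of these, 8 were at least 2-fold higher in the quinquefasciatus library and 4 in the molestus library. The opsin-1 models CPIJ011571 and CPIJ012052, light receptors that may be undercounted if they are near-identical copies, were 1.94-fold (1.92 to 1.96) and 1.93-fold (1.92 to 1.95) higher in the quinquefasciatus library. Opsin-2 (CPIJ005000) was 4.81-fold higher (4.40 to 5.27) and the arrestin CPIJ012143, which shuts off activated opsin, 3.09-fold higher (3.05 to 3.12). The list also took in arrestin domain-containing proteins and rhodopsin-related enzymes, and without both, an alternative chosen after seeing the data, the median was -0.95 over 16 models with an interval that included 0 (-1.55 to 0.31). Circadian clock genes went both ways, with a median of 0.14 (-1.50 to 1.22) over 12 models, a mean of -0.01, a negative median under both rescalings and a median of -1.26 over 9 models at a minimum of 10 RPKM. Timeless protein (CPIJ007082) and cryptochrome-2 (CPIJ009455), components of the clock's feedback loop, were 2.46-fold (2.23 to 2.73) and 4.69-fold (3.92 to 5.66) higher in the quinquefasciatus library, while other models of the same names, timeless (CPIJ000660) and cryptochrome-2 (CPIJ017734), were 2.42-fold (2.10 to 2.79) and 1.93-fold (1.65 to 2.25) higher in the molestus library. The timeless interacting protein CPIJ017219, a factor of DNA replication, was 8.14-fold higher in the molestus library (5.59 to 12.2).

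Salivary proteins were at least 2-fold higher in the quinquefasciatus library for 11 of 20 models and in the molestus library for 1, with a median of -1.11 (-2.19 to -0.61) at percentile 0.10, and -0.92 with the 6 members at 0 reads in 1 library at the floor. It was -0.70 over 32 models without a filter and -1.36 at a pseudocount of 0.1. The list's text pattern also took in glutathione S-transferases named D7, and without them, chosen after seeing the data, the median was -1.11 (-2.34 to -0.50) over 18 models. A D7 protein (CPIJ014551), of a family that binds host amines during blood feeding, had 2 molestus and 959 quinquefasciatus reads, a ratio of 462 (127 to 3817). The most abundant salivary model, CPIJ018794, differed little, at 896 against 756 RPKM or 1.18-fold higher in the molestus library (1.14 to 1.23), and rescaling by the median ratio turned it below 1-fold.

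Cytochrome P450s, oxidases of hormones and foreign compounds, were at least 2-fold higher in the quinquefasciatus library for 47 of 88 models and in the molestus library for 7. Their median of -1.04 (-1.28 to -0.79) lay below all matched lists, and was -1.74 over 28 models at a minimum of 10 RPKM, -0.41 without a filter and -1.48 at a pseudocount of 0.1. The P450s CPIJ019751 and CPIJ003082 were 58.2-fold (37.5 to 95.7) and 14.5-fold (12.8 to 16.5) higher, and CPIJ005957, described as cytochrome P-450 and outside the list's pattern, 119-fold higher (80.1 to 187). Glutathione transferases, which conjugate toxic compounds, had a median of -0.75 (-1.27 to -0.15; -0.65 with the 2 members at 0 reads in 1 library at the floor) over 35 models at percentile 0.03, with 15 at least 2-fold higher in the quinquefasciatus and 3 in the molestus library. Their median was -0.44 over 20 models at a minimum of 10 RPKM and -1.04 after rescaling by the median ratio. CPIJ002680 was 12.7-fold higher in the quinquefasciatus library (8.22 to 20.6) and CPIJ002679 6.75-fold higher in the molestus library (3.65 to 13.6). Esterases had a median of -0.62 (-1.26 to -0.38) over 17 models, 7 of them at least 2-fold higher in the quinquefasciatus and 0 in the molestus library, at percentile 17.5. The median was -2.89 over 3 models at a minimum of 10 RPKM and -0.26 without a filter. Juvenile hormone esterase (CPIJ011169), which degrades juvenile hormone, was 47.5-fold higher in the quinquefasciatus library (27.0 to 92.4).

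Of 108 compared cytosolic ribosomal protein models, 95 were lower in the molestus library, 30 of them at least 2-fold, and 4 were at least 2-fold higher there. The median was -0.81 (-0.88 to -0.74), and -1.09 after rescaling by the median ratio, and it lay below all matched lists. L18 (CPIJ000205) and L17 (CPIJ015624) were 2.40-fold (2.37 to 2.43) and 1.94-fold (1.91 to 1.96) higher in the quinquefasciatus library. The S24 model CPIJ009083 was 61.4-fold higher in the molestus library (41.7 to 94.3), while the reads summed over all 5 models named S24 had a log2 ratio of -0.83 (-0.87 to -0.80), and the other 4 without it -1.08 (-1.12 to -1.04). The list of the mitochondrial respiratory chain, which makes most of the cell's ATP, had a median of -0.69 (-0.84 to -0.56) over 74 models, below all matched lists, with 19 at least 2-fold higher in the quinquefasciatus and 1 in the molestus library. Its text pattern also took in vacuolar ATP synthase subunits, which are not mitochondrial, and without them, an alternative chosen after seeing the data, the median was -0.68 (-0.85 to -0.55) over 60 models. The ATP synthase lipid-binding protein (CPIJ008101) was 3.62-fold higher in the quinquefasciatus library (3.57 to 3.68), at 5394 against 1489 RPKM. Glycolysis genes had a median of -0.74 (-0.97 to -0.19) over 13 models at percentile 2.97 (-1.04 after rescaling by the median ratio and -0.60 with the member at 0 reads at the floor), with 2 at least 2-fold higher in the quinquefasciatus and 0 in the molestus library. Enolase (CPIJ000948) was 2.12-fold higher in the quinquefasciatus library (2.07 to 2.18).

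Muscle genes had a median of -0.54 (-1.04 to -0.30) over 67 models at percentile 0.04, with 27 at least 2-fold higher in the quinquefasciatus and 5 in the molestus library. Muscle actin (CPIJ016462) and troponin T (CPIJ009743), parts of the contractile filaments, were 2.06-fold (2.0 to 2.11) and 3.25-fold (3.10 to 3.40) higher in the quinquefasciatus library. Paramyosin (CPIJ014365) was 1.65-fold higher in the molestus library (1.58 to 1.71). Cuticle proteins had a median of -0.88 (-1.68 to -0.50) over 31 models at percentile 0.12, with 15 at least 2-fold higher in the quinquefasciatus and 4 in the molestus library. The median was -2.20 over 8 models at a minimum of 10 RPKM and -0.31 over 79 without a filter. Adult cuticle protein 1 (CPIJ003468) was 6.61-fold higher in the quinquefasciatus library (5.70 to 7.70).

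Immune effectors and recognition proteins had a median of -0.61 (-0.75 to -0.20; -0.31 without a filter) over 85 models at percentile 0.13, with 28 at least 2-fold higher in the quinquefasciatus and 14 in the molestus library. The list's text pattern also took in thioesterases and beta-1,3 glycosyltransferases. Without them, an alternative chosen after seeing the data, the median was -0.68 (-1.03 to -0.51) over 68 models. The antimicrobial peptide cecropin-B1 (CPIJ005108) was 1.57-fold higher in the quinquefasciatus library (1.49 to 1.64), and peptidoglycan recognition protein 2 (CPIJ007162), which binds bacterial cell walls, 33.7-fold higher (16.1 to 84.7). Defensin-C (CPIJ001276) was 3.45-fold higher in the molestus library (2.11 to 5.83). Genes of lipid transport and synthesis had a median of -0.70 (-0.94 to -0.20; -0.35 without a filter) over 38 models at percentile 0.13, with 11 at least 2-fold higher in the quinquefasciatus and 2 in the molestus library. Fatty acid synthase (CPIJ005595) was 4.08-fold higher in the quinquefasciatus library (3.83 to 4.35). A protein of the surface of lipid storage droplets (CPIJ018160) was 3.82-fold higher in the molestus library (3.68 to 3.97), at 984 against 257 RPKM.

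Among described models, the largest log2 ratio of RPKM + 1 in the molestus direction belonged to 1-O-acylceramide synthase (CPIJ010977), an enzyme of lipid acylation, at 3223 against 62.0 RPKM or 52.0-fold higher (48.6 to 55.7). A tuberin model (CPIJ019306), a brake on growth signalling, was 86.0-fold higher (46.5 to 180) and a no-on-transient A model (CPIJ010197), an RNA-binding protein, 66.1-fold higher (39.2 to 121). In the other direction a collagenase (CPIJ016348) had 0 molestus and 1474 quinquefasciatus reads, at least 473-fold higher against the floor of 3 reads per library. An ovomucoid (CPIJ010521), named for a class of protease inhibitors, and a galactose-specific C-type lectin (CPIJ006818) also had 0 molestus reads and were at least 84.7-fold and at least 52.6-fold higher in the quinquefasciatus library. A gene absent or diverged in molestus could also give 0 reads, which was not tested. The 4f2 cell-surface antigen (CPIJ019692), named for a subunit of amino acid transporters, was 38.8-fold higher there (35.2 to 42.8), at 908 against 23.4 RPKM.

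**Figure D3:**
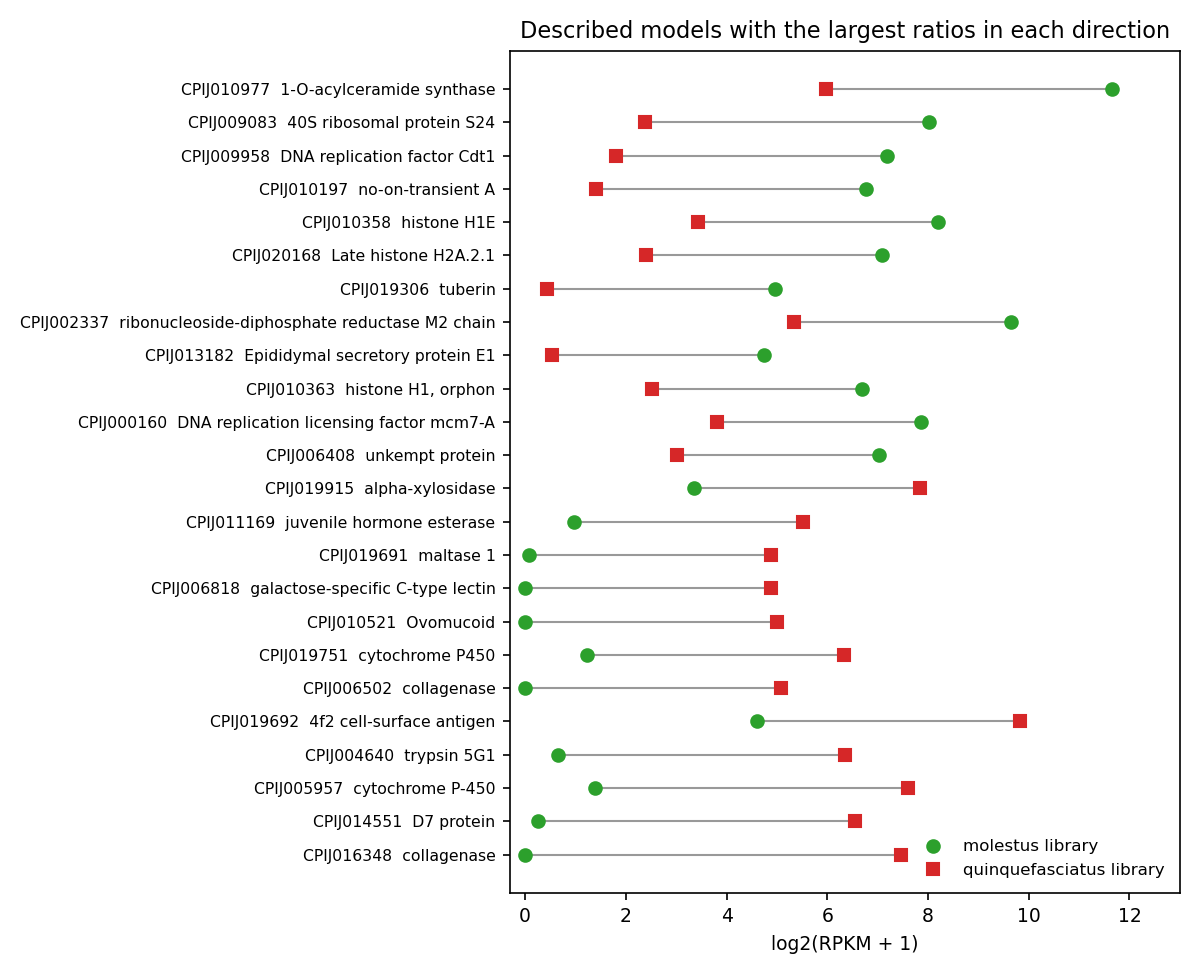
Levels, as log2(RPKM + 1), of the 12 described models with the largest ratio in each direction in the molestus library (green circles) and the quinquefasciatus library (red squares), 1 library each. At the ends of the order, which follows the log2 ratio of RPKM + 1, stand 1-O-acylceramide synthase, 52.0-fold higher in the molestus library, and a collagenase with 0 molestus reads, at least 473-fold higher in the quinquefasciatus library.

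Models with more than 3 reads in 1 library and 0 in the other numbered 242 for the molestus and 569 for the quinquefasciatus library. At more than 10 reads they numbered 73 and 163, and with at least 50 reads 5 and 18. The 10 most abundant models took 8.20% (8.18 to 8.22) of molestus and 12.3% (12.32 to 12.36) of quinquefasciatus reads, and the 100 most abundant took 29.5% (29.48 to 29.53) and 44.7% (44.67 to 44.73). Elongation factor 1-alpha (CPIJ009303), a part of the translation machinery, was the most abundant model of the molestus library by RPKM, though not by reads, at 9102 against 10921 RPKM. The heat shock 70 kDa protein cognate CPIJ008915, a chaperone, stood at 7320 against 4011 RPKM, 1.82-fold higher in the molestus library (1.81 to 1.84).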

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

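Some of the tests below were chosen only after the result was seen. These were the removal of the most abundant models, both comparisons of tissue markers and the sum of the other S24 models. The share of models above 10 reads, and the numbers from counting error beside it, were also chosen then. Reads piled on a small part of a model were sought in the covered percent, a column that the comparisons of levels do not use. Models with at least 1000 reads over under 50% of their length numbered 10 in the molestus and 16 in the quinquefasciatus library. A hypothetical protein (CPIJ009609), singled out after its values were seen, had 1030 molestus reads over 18.4% of its length against 13 quinquefasciatus reads over 50.4%. Another (CPIJ013099), singled out in the same way, had 1930 reads over 38.6% against 12 reads over 18.1%. Calmodulin (CPIJ007602), a calcium sensor also named after its values were seen, had 3492 quinquefasciatus reads over 46.1% of its length against 262 molestus reads over 45.6%.

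Cell cycle and histone lists were higher, and digestive, odorant binding and ribosomal protein lists lower, in the molestus library. After rescaling without the 100 most abundant models of either library the cell cycle median was 1.47 (0.80 to 1.88) and the trypsin median -1.24 (-1.52 to -0.85). This could not decide whether a few abundant models taking most reads were a cause. The rescaling moved all ratios by a common -0.24, and a common shift cannot remove differences of opposite direction. The values show only that a shift of this size left both directions in place. Loss of molestus reads on models of the other taxon stays open for the lower lists, since their 30 members with 20 to 200 reads in both libraries were covered over 3.68 percentage points more of their length in the molestus library at matched reads (-2.33 to 7.63), but this measure followed the ratio in general, at 3.16 (1.84 to 4.39) for models at least 2-fold higher in the quinquefasciatus and -4.13 (-5.38 to -3.47) for those higher in the molestus library, so the test, with its bound of 5 points set beforehand, could not decide this. A lower share of sense organ, eye and muscle tissue in the molestus pool stays open as part of the cause. The medians of 6 odorant binding proteins (-1.68), 6 opsins (-1.27) and 14 troponins, tropomyosins and muscle actins (-1.41) at a mean of at least 10 RPKM lay within 0.413 of each other, and within 0.357 over all compared members. These markers were picked after the result was seen, and odorant binding proteins are themselves in the pattern. The whole lists of muscle (-0.54, 67 models), phototransduction (-0.67, 30 models) and neural genes (-0.35, 71 models) were lower by less. The opsin interval over all compared members was -2.33 to 0.31. Whether the gut was lower by the same amount depended on the filter, with trypsins and chymotrypsins (antitrypsins left out) at -2.45 (-3.48 to -2.03, 16 models) against -1.53 (-1.78 to -1.10) of those 26 markers, and at -1.19 (-1.74 to -0.73, 59 models) against -1.40 (-1.59 to -1.10) of 39 markers over all compared members. A difference between the taxa, or in the state of the females such as developing eggs, stays open and untested with 1 library each.

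More models had over 3 reads in the quinquefasciatus library and 0 in the molestus library (569) than the reverse (242). Levels near the detection limit are argued against as the whole cause of this excess. Counting error alone at equal levels would give 41.4 such models in the quinquefasciatus and 34.6 in the molestus library. Above 10 reads it would give 0.17 and 0.11, against 163 and 73 found. Of these 236 models 69.1% (62.7 to 74.9) were in the quinquefasciatus library, which held 50.9% of the reads. That share of reads is not the share that counting error would give. Loss of molestus reads by sequence difference stays open, since the difference in covered length at matched reads, -0.63 percentage points (-0.94 to -0.30), molestus minus quinquefasciatus, was taken over 3313 models with 20 to 200 reads in both libraries, a set that by its design holds none of these models. The test, with its bound of 5 points set beforehand, could therefore not decide this pattern, and genes absent or diverged in 1 taxon stay open and untested.

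The S24 model CPIJ009083 was 61.4-fold higher in the molestus library while the ribosomal protein list was lower. Reads taken from other copies stay open as a cause, since the other 4 models named S24 summed to 8060 against 17731 reads, a log2 ratio of -1.08 (-1.12 to -1.04), below the median of -0.80 of the 103 ribosomal models of other names but above their 2.5 percentile of -1.62. A difference between the taxa in which copy is used stays open and untested.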

How the results depend on the processing

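Alternatives were fixed before the data were examined, except the changed list patterns, chosen after seeing the data. None of the results with a called direction reversed, but much of this was fixed in advance. A direction was called for named models at least 2-fold apart and for lists at either end of the matched lists. Percentile 1.40 (phototransduction) was called and 2.97 (glycolysis) was not, and germline genes were called although their interval included 0. Each rescaling shifted all ratios by -0.30 or -0.24. This could not turn lower lists or the called higher medians of 1.26, 1.69 and 1.78. The direction was kept for 28 of 28 list medians at a pseudocount of 0.1, 27 without a filter, 25 of 27 at 10 RPKM (storage proteins gave no value there) and 26 of 28 under each of the median ratio and TMM rescalings. The exceptions, none with a called direction, were yolk and clock genes under the rescalings, clock genes and serpins at 10 RPKM and genes named for the testis or sperm without a filter. The rescalings turned the balance of the 2-fold counts, as printed beside them. Among the 190 named models the direction was kept for 190 at a pseudocount of 0.1, 188 under TMM and 185 under the median ratio. A pseudocount cannot turn the sign of a single ratio. The 190 of 190 was therefore fixed in advance, and the 28 of 28 list medians nearly so. Models at least 2-fold higher in the molestus library numbered 1326 at a pseudocount of 10 and 615 at 4-fold, and in the quinquefasciatus library 618, 508 and, at 10 RPKM, 1139. Models in 1 library numbered 73 (molestus) and 163 above 10 reads. At a pseudocount of 0.1 the medians were -1.84 (trypsins), -1.75 (odorant binding), -1.48 (P450s) and 2.75 (histones). Without a filter they were -0.51 (trypsins), -0.41 (P450s), -0.31 (cuticle) and -0.69 (ribosomal). At 10 RPKM they were -2.31 (trypsins), -0.95 (phototransduction), -1.74 (P450s) and -2.20 (cuticle). Rescaling by the median ratio gave -0.97 (lipid), -1.63 (odorant binding), -1.09 (ribosomal) and -0.98 (respiratory chain), and TMM gave -1.59, -1.04 and -0.93 for the last 3. Phototransduction without arrestin domain-containing proteins and rhodopsin-related enzymes gave -0.95. The pattern that reads P450 or P-450 gave -1.06, trypsins without antitrypsins -1.19, and the immune list without thioesterases and glycosyltransferases -0.68. The respiratory chain without vacuolar ATP synthase gave -0.68, and salivary proteins without glutathione S-transferases -1.11. Pearson's r was 0.789 at a pseudocount of 0.1 and 0.893 without a filter, where Spearman's rho was 0.879. Of summed RPKM the 10 most abundant models took 7.46% (molestus) and 11.6%, and the 100 most abundant 35.5% and 52.4%. The pseudocount and the filter change how far low models are pulled to 0 or enter a list, and the cause of the other shifts was not tested. No paired analysis was possible because each taxon had 1 library, and no replicate could be left out. A median of 94 or 86 reads per model limits what can be said of single low models.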

Other observations

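Heat shock proteins, chaperones of protein folding, had a median of 0.51 (-0.09 to 0.73) over 40 models at percentile 77.9, with 11 at least 2-fold higher in the molestus and 6 in the quinquefasciatus library. Their median was 0.21 after rescaling by the median ratio and 0.27 by TMM. The heat shock protein CPIJ011244 was 5.92-fold higher in the molestus library (5.46 to 6.42) and a heat shock 70 kDa protein (CPIJ019868) 3.77-fold higher (3.61 to 3.93). Neural genes had a median of -0.35 (-0.73 to -0.01) over 71 models at percentile 10.0, with 8 and 19 at least 2-fold higher in the molestus and quinquefasciatus libraries, and of -0.0017 over 24 models at a minimum of 10 RPKM and -0.17 without a filter. Synaptotagmin (CPIJ004781), the calcium sensor of synaptic vesicles, was 4.67-fold higher in the quinquefasciatus library (3.89 to 5.63), and synaptogyrin-1 (CPIJ019269), a vesicle membrane protein, was 2.79-fold higher in the molestus library (2.49 to 3.12). Hormone signalling genes had a median of -0.21 (-0.82 to 0.40) over 20 models at percentile 12, with 4 and 3 at least 2-fold higher, and the ecdysone receptor (CPIJ002963), the nuclear receptor of the moulting hormone, was 2.78-fold higher in the molestus library (2.36 to 3.29). Serpins and clip proteases had a median of -0.26 (-0.62 to 0.58) over 17 models at percentile 23.0, with 2 and 3 at least 2-fold higher, and turned positive (0.58) at a minimum of 10 RPKM. Genes named for the testis or sperm had a median of 0.47 (-0.56 to 1.10) over 21 models at percentile 83.9, with 6 and 3 at least 2-fold higher, and -0.06 without a filter. The most abundant of them, nuclear autoantigenic sperm protein (CPIJ009638), a histone chaperone, was 3.89-fold higher in the molestus library (3.74 to 4.06). Transposable elements had 2 compared models, both within 2-fold, with a median of -0.67.

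A scan of the 207 words that occur in the descriptions of at least 15 compared models was made after seeing the data, and it describes these libraries without a test. Each group below holds the models with that word in their description, and each median stands against the median of matched random lists. Helicases, which unwind DNA or RNA, had 36 of 83 models at least 2-fold higher in the molestus library and 2 in the quinquefasciatus library, with a median of 0.85 (0.61 to 1.09) against 0.36. Polymerases had 34 of 62 and 2, with a median of 1.09 (0.61 to 1.40) against 0.38, and 10 of the 62 also belong to a fixed list. Models with ubiquitin in their description had 40 of 104 and 3, with a median of 0.80 (0.59 to 0.98) against 0.36. Models with glucuronosyltransferase in their description, mostly enzymes that make compounds soluble for excretion, had 13 of 23 at least 2-fold higher in the quinquefasciatus library and 2 in the molestus library, with a median of -1.49 (-2.30 to -0.31) against 0.15. Venom allergen proteins, a family also found in mosquito saliva, had 10 of 15 and 0, with a median of -1.58 (-2.42 to -0.48) against 0.04. Lipases had 11 of 19 and 0, with a median of -1.23 (-1.57 to -0.48) against -0.26, and peritrophins, proteins of the membrane that lines the gut, had 9 of 15 and 3, with a median of -1.21 (-1.96 to -0.15) against -0.05.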
